A study of Mus musculus with 8 samples.

How the data were processed

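Gene expression was measured with Affymetrix 3' expression arrays in mouse cells that were being reprogrammed. Per the labels, total RNA was extracted with TRIZOL, its integrity was checked, it was purified on RNeasy columns with DNase, and it was amplified into biotin-labelled cRNA with the 3' IVT Express kit. There were 8 arrays in 4 groups of 2: DMSO at day 3, CSA at day 3, DMSO at day 6 and CSA at day 6. The series design text calls the 2 arrays of a group independent biological repeats, and a group was read from each sample's own label.

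The authors deposited 1 log2 signal per probe set and array, for 45037 probe sets. The submitters' processing notes name MAS5 and give no version; the scaling target and the treatment of low signals are not given in the sources used here. MAS5 reduces the probes of a probe set to 1 signal and scales each array by a constant. In the deposited log2 signals the mean of the anti-logged values, with 2% trimmed at each end, lay between 496.8 and 497.5 on every array, and between 110 and 259 values per array were exactly 0, the lowest value in the table. The arrays were not quantile normalized: the median log2 signal ran from 6.15 to 6.53. Detection calls and control probe sets were not used here, so RNA degradation was not measured, and scan dates or array batches are not given in the sources used here.

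The comparisons, gene lists, the rule for named genes and the other settings to be run were fixed before the data were examined. That plan provided for linear signals with a pseudocount, or for log2 values used as they stood. The values were already log2, so the pseudocount was 0, and the smaller and larger pseudocounts and the floor written down for linear values were void. In their place, pseudocounts of 8 and 32 on the anti-logged signals and a floor at a log2 signal of 5 were added after seeing the data. A log2 difference of dim probe sets is compressed or inflated by the floor and by background.

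Probe sets with a mean log2 signal over all arrays at or above the 40th percentile, 5.37, were tested, which left 27022. The platform annotation gave 1 gene symbol for 34945 of all probe sets, several for 932, and did not list 9160; of those with 1 symbol, 34741 were matched to a current gene by Entrez ID with 0 symbols changed, and 204 kept the annotation's name. No gene was named from a probe set with several symbols. Each of 12529 genes was represented by its tested probe set with the highest mean signal, and 6066 of them had more than 1 tested probe set. Among genes past the threshold with several tested probe sets, another probe set was past it in the opposite direction for 4 of 935 genes for CSA at day 3, 3 of 880 at day 6, 1 of 408 for the interaction, 190 of 3246 for the days in DMSO and 83 of 2547 for the days in CSA.

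Tests were run with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 8 arrays, which leaves 4 residual degrees of freedom, followed by empirical Bayes moderation with an intensity trend in the prior variance. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05. The contrasts were CSA against DMSO at day 3 and at day 6, the difference between these effects (the day by treatment interaction), and day 6 against day 3 in DMSO and in CSA. CSA against DMSO over both days was fitted with day as a covariate. Of 40 gene lists, the 37 with at least 4 tested members were tested with camera over the gene representatives, with a preset inter-gene correlation of 0.01 and adjustment over the 37 lists. Beside it camera was run with the correlation estimated per list. That setting also bases its p-values on the 4 residual degrees of freedom rather than on the number of genes. A call lost there need not be lost through the correlation alone. Limma's rotation test fry, which does not compare a list with other genes, was run as well. Counts of genes were also adjusted over the list alone. The 3 lists too short to test held the reprogramming factors, early demethylated germline genes and lymphoid genes.

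The genes named are the up to 10 with the largest rise and fall among genes past the threshold whose arrays did not overlap between the groups at each day (up to 5 for the interaction and the comparisons of days), up to 4 members of each list with the smallest p, and a fixed set of reprogramming, epithelial, mesenchymal and calcineurin genes. Sox2, Nanog and Fut4 of that set were below the filter, and Ppia and Gapdh had only probe sets with several symbols.

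The pipeline was tested on simulated data with the real means of the 27022 probe sets, of which 200 were changed, 50 for each size and direction. Spreads were drawn from limma's fitted prior with its intensity trend, and the noise was normal. The simulated data thus obey the fitted model, so the numbers of unchanged probe sets called cannot test that model or its trend. For CSA against DMSO at day 3 it recovered 46% of 2-fold and 78% of 4-fold changes, with 0 in the wrong direction, and called 5 unchanged probe sets. For the interaction it recovered 29% and 68% and called 7 unchanged probe sets. In the comparison at day 6, which held no simulated change, it called 0. With 2 arrays per group the number of arrays limits the precision, and it does so most for dim probe sets: the median within-group SD was 0.58 for mean log2 signals between the filter and 6, 0.314 between 6 and 8, 0.147 between 8 and 10, and 0.0823 above 10.

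The alternatives were no filter, a filter at the 60th percentile, quantile normalization, centring of each array on its median, moderation without the trend or robust moderation, a fit of only the 4 arrays compared, exclusion of probe sets whose IDs end in _s_at, _x_at or _a_at, which can read several transcripts or genes, the mean of a gene's probe sets for lists, the replicate number as a block, a 2-fold minimum, and leaving out each array in turn. Probe sets with these endings are called below probe sets that can read several genes, although some may read several transcripts of 1 gene. A fit without 1 array leaves its group with 1 array, which is then assumed to vary like the other groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.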

Results

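The series profiled mouse cells of C57BL/6 background during reprogramming in a secondary OSKM system, in which cells carry Oct4 (Pou5f1), Sox2, Klf4 and Myc under the control of doxycycline and start to reprogram when it is added. The cells were grown in embryonic stem cell medium with 15% serum and 100 units per ml of leukemia inhibitory factor, and the labels write the doxycycline dose as 2 mg per ml. They received CSA, written as 10 mM, or the solvent DMSO. CSA stands for cyclosporin A, which binds cyclophilins and inhibits the phosphatase calcineurin, the activator of NFAT transcription factors. RNA was collected at day 3 and day 6 from 2 biological repeats per treatment and day, 8 arrays in all, so the number of arrays limits the precision of every comparison. The question was which genes differ between control cells and cells under calcineurin-NFAT inhibition at each day.

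Over the 27022 tested probe sets the correlation of log2 signals was 0.968 to 0.974 between the arrays of a group, 0.957 to 0.963 between treatments at the same day, and 0.918 to 0.943 between days. The first principal component, with 48.5% of the variance, separated the days, and the second, with 13.9%, separated the treatments at both days. Median signals of the tested probe sets were 8.22 to 8.24 at day 3 and 8.44 to 8.47 at day 6. Values after ± are limma's moderated standard errors for groups of 2 arrays. They rest on the spread within all 4 groups, drawn toward the intensity trend, and not on the 2 groups compared alone.

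**Figure D1:**
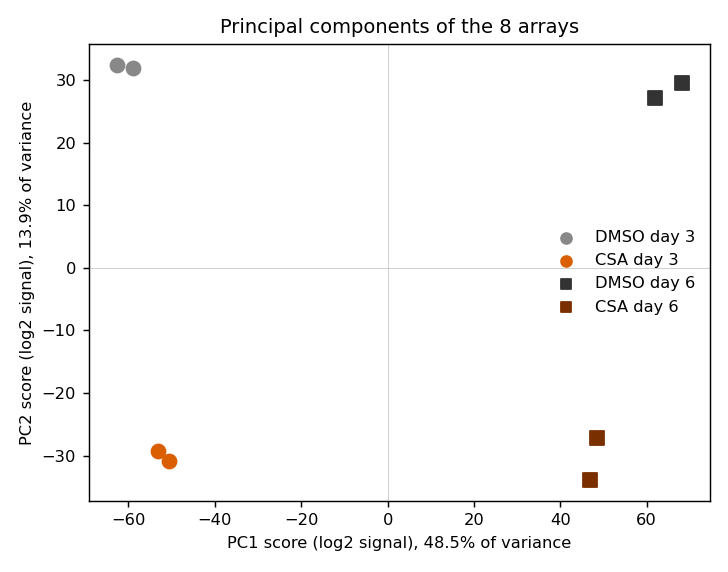
Scores of the 8 arrays on the first and second principal components of the log2 signals of the tested probe sets. The first component (48.5% of the variance) ran from -62.7 to -50.5 at day 3 and from 46.8 to 68.2 at day 6. On the second (13.9%) the DMSO arrays lay between 27.2 and 32.4 and the CSA arrays between -33.9 and -27.2.

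The first comparison asked what CSA changed at day 3. Genes of the unfolded protein response rose as a list. The lists of G2 and mitosis and of DNA replication were lower, calls that ended when the correlation was estimated (adjusted p = 0.0556 with an estimated correlation and adjusted p = 0.0773 with an estimated correlation). Aldh1l2, a mitochondrial enzyme of folate metabolism, rose 15.1-fold, by 3.92 ± 0.14 on the log2 scale (adjusted p = 1.86e-07, n = 2 arrays per group), from a mean log2 signal of 6.58 to 10.5. Slc7a11, the cystine transporter, rose by 2.67 ± 0.48 (adjusted p = 0.00563, or 0.0573 without CSA replicate 1), and Alpl, the alkaline phosphatase used as an early marker of reprogramming, by 1.92 ± 0.29 (adjusted p = 0.00217). The list of early reprogramming markers did not pass with camera at this day. In all, 2588 probe sets passed the threshold, 1445 higher and 1143 lower with CSA, of which 226 and 117 differed at least 2-fold. They represented 895 genes that rose and 692 that fell.

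Of 28 tested genes of the unfolded protein response list 18 rose, and 21 did when adjusted over the list alone (median 0.44, camera adjusted p = 2.84e-14). Examples were Chac1 at 1.95 ± 0.17, the ER co-chaperone Dnajb9 at 1.56 ± 0.08, Herpud1 at 1.42 ± 0.08 and the transcription factor Xbp1 at 0.70 ± 0.07. This was the 1 list at day 3 whose call held with an estimated correlation (adjusted p = 0.0320 with an estimated correlation). In the list of the G2 phase and mitosis 27 of 35 genes fell, 34 adjusted over the list alone, with a median of -0.63 and a camera adjusted p of 1.46e-22 (adjusted p = 0.0556 with an estimated correlation). The kinase Aurka changed by -1.07 ± 0.09, Ckap2 by -0.97 ± 0.10 and the cyclin-dependent kinase Cdk1 by -0.91 ± 0.09. In the DNA replication list 20 of 34 fell, 28 adjusted over the list alone (median -0.52, camera adjusted p = 7.46e-19, and adjusted p = 0.0773 with an estimated correlation). They included the helicase subunits Mcm5 at -0.98 ± 0.07 and Mcm7 at -0.69 ± 0.07.

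The epithelial list was higher at this day, although most of its genes did not pass: 14 of 37 rose and 1 fell, 20 and 5 adjusted over the list alone (median 0.36, camera adjusted p = 6.29e-05, and adjusted p = 0.0773 with an estimated correlation). The desmosomal cadherin Dsg2 rose by 1.84 ± 0.13, Dsc2 by 1.23 ± 0.12 and the transcription factor Ehf by 1.19 ± 0.13, while the keratin Krt19 changed by -0.81 ± 0.11. E-cadherin (Cdh1) rose by 0.29 ± 0.07 (adjusted p = 0.0192), a call that ended when either DMSO or CSA array of day 3 was left out (adjusted p = 0.0608 and 0.0673 without DMSO replicate 1 or 2, 0.0622 and 0.157 without CSA replicate 1 or 2). In the keratinocyte list 4 of 15 rose, 5 adjusted over the list alone, among them Krt17 at 1.32 ± 0.15 and Krt16 at 0.69 ± 0.07 (camera adjusted p = 0.0159, and adjusted p = 0.497 with an estimated correlation). Glycolysis genes were lower, with 5 of 20 past the threshold, and 2 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.00642, and adjusted p = 0.172 with an estimated correlation). Eno3, an enolase, changed by -1.39 ± 0.09 and the glucose transporter Slc2a1 by -0.84 ± 0.07. Of 15 heat shock genes 6 fell, also 6 adjusted over the list alone (camera adjusted p = 0.00344, and adjusted p = 0.497 with an estimated correlation), such as the small heat shock protein Hspb1 at -0.45 ± 0.07. Oxidative phosphorylation genes passed with a median of -0.08 over 46 genes, 1 up and 3 down, also 1 and 3 adjusted over the list alone (camera adjusted p = 0.0351, and adjusted p = 0.550 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.463, median -0.03), without the trend (0.135), without DMSO replicate 2 (0.0644) and without CSA replicate 2 (0.188, median -0.05). The keratinocyte call ended without the trend (0.0618), with the mean of a gene's probe sets (0.116) and without DMSO replicate 1 (0.0782), and the heat shock and glycolysis calls ended without the probe sets that can read several genes (0.0669 and 0.368).

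Many of the largest changes at day 3 were of dim genes. Besides Aldh1l2 and Slc7a11, the genes with the largest rise were B4galnt2, Mroh4, Gm11545, Pdlim4, Cd160, Cxxc4, P2rx3 and Sct, between 3.82 and 2.48, most of them from DMSO means near background, such as 2.94 for Mroh4 and 3.09 for Pdlim4. Those with the largest fall were Afap1l1, Trib1, Grb7, Saxo1, Tril, Syndig1, 4930444M15Rik, Mcam, Crybb3 and 1700029J07Rik, between -3.05 and -2.41. Without the trend in the prior variance 442 probe sets passed at day 3, and the calls of B4galnt2, Mroh4, Pdlim4, Sct, Trib1, Grb7, Saxo1, Tril, Syndig1, 4930444M15Rik, Mcam, Krt19, Hspb1 and Cdh1 ended. The calls of B4galnt2, Trib1, Grb7 and Syndig1 also ended without the filter and under quantile normalization. With a floor at a log2 signal of 5 Pdlim4 was at 1.06 (adjusted p = 0.121), Cxxc4 at 0.96 (0.108) and 4930444M15Rik at -1.04 (0.110). The floor or a pseudocount of 32 moved all of these largest changes except those of Aldh1l2, P2rx3 and 1700029J07Rik by more than 1.5 times. Leaving out some 1 array of day 3 ended the calls of B4galnt2, Mroh4, Cd160, Sct, Trib1, Grb7, Saxo1, Tril, Syndig1, 4930444M15Rik and Crybb3, and the fit of only the 4 arrays compared ended those of B4galnt2, Pdlim4, Cxxc4, Trib1, Grb7, Saxo1, Tril, Syndig1, 4930444M15Rik and Crybb3. The count was 1180 and 1076 without CSA replicate 1 or 2 of day 3, and 1672 without the probe sets that can read several genes.

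At day 6 the comparison asked the same of cells later in reprogramming. The list of contractile smooth muscle genes was higher, and the epithelial and pluripotency lists were lower. These calls ended when the correlation was estimated (adjusted p = 0.0561 with an estimated correlation for smooth muscle and adjusted p = 0.0967 with an estimated correlation for each of the others). Of the 10 genes with the largest rise, 7 were late cornified envelope genes: Lce3c, Lce1d, Lce1h, Lce1f, Lce1a1, Lce3a and Lce1a2. They were no fixed list and were not tested as a group. Lce1d rose by 3.92 ± 0.31 (adjusted p = 2.92e-05), from a mean log2 signal of 6.13 to 10.0. Oct4 (Pou5f1) fell by 1.07 ± 0.18 (adjusted p = 0.00435), and Cdh1 fell by 0.50 ± 0.07 (adjusted p = 0.000879). The Pou5f1 probe set was not checked for reading the transgene, so the endogenous gene and the transgene are not told apart here. In all, 2612 probe sets passed, 1380 higher and 1232 lower with CSA, of which 257 and 167 differed at least 2-fold; they represented 803 genes that rose and 766 that fell.

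The unfolded protein response list was again higher, with 14 of 28 genes past the threshold, 16 adjusted over the list alone (median 0.28, camera adjusted p = 6.23e-11, and adjusted p = 0.0499 with an estimated correlation, the 1 list at day 6 that held). Ddit3, which encodes the stress factor CHOP, rose by 1.94 ± 0.15, Chac1 by 1.91 ± 0.17 and Dnajb9 by 1.30 ± 0.08. Contractile genes of smooth muscle rose, 10 of 17 and also 10 adjusted over the list alone (median 0.46, camera adjusted p = 2.29e-08, and adjusted p = 0.0561 with an estimated correlation). Tagln rose by 1.02 ± 0.10, the smooth muscle actins Actg2 by 0.77 ± 0.10 and Acta2 by 0.74 ± 0.08. Antioxidant genes under NRF2 were higher, 8 of 24, or 11 up and 1 down adjusted over the list alone (camera adjusted p = 0.000171, and adjusted p = 0.0967 with an estimated correlation). Heme oxygenase Hmox1 rose by 1.25 ± 0.17 and the metallothionein Mt1 by 1.06 ± 0.07.

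The pluripotency network list was lower, with 6 of 24 genes past the threshold, and 1 up and 10 down adjusted over the list alone (median -0.50, or -0.31 without the filter, camera adjusted p = 0.00156, and adjusted p = 0.0967 with an estimated correlation). The de novo DNA methyltransferase Dnmt3b changed by -1.27 ± 0.13, and Tet2 by -0.52 ± 0.09. At day 3 this list did not pass with camera. Of its genes, Dnmt3b (-0.87), Mybl2 (-0.65), Fgf4 (-0.52) and L1td1 (-0.45) were already past the threshold and lower at day 3, and Tet2 (0.40) higher. Markers of early reprogramming fell in 5 of 20 genes, 9 adjusted over the list alone (median -0.40, camera adjusted p = 0.000826, and adjusted p = 0.0967 with an estimated correlation), and without the probe sets that can read several genes this call ended (adjusted p = 0.0831, median -0.23). Epithelial genes fell in 10 of 37, 11 adjusted over the list alone (median -0.33, camera adjusted p = 0.00170, and adjusted p = 0.0967 with an estimated correlation). The matriptase gene St14 changed by -0.83 ± 0.09, its inhibitor Spint2 by -0.65 ± 0.08 and the keratin Krt8 by -0.53 ± 0.06. Chromatin modifiers were lower, 1 up and 7 down of 30, or 2 and 12 adjusted over the list alone (camera adjusted p = 0.000519, and adjusted p = 0.0967 with an estimated correlation); Chd4 changed by -0.48 ± 0.09, a call that ended without DMSO replicate 2 (adjusted p = 0.0565). Immediate early genes were lower, 1 up and 9 down of 24, or 4 and 11 adjusted over the list alone (camera adjusted p = 0.00203, and adjusted p = 0.157 with an estimated correlation). The orphan nuclear receptor Nr4a1 changed by -0.84 ± 0.07 and Jun by -0.53 ± 0.09, whereas Fosl1 rose by 0.99 ± 0.13. In the G2 and mitosis list 6 of 35 fell, 9 adjusted over the list alone (median -0.22, camera adjusted p = 4.38e-05, and adjusted p = 0.157 with an estimated correlation).

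Interferon response genes had a median of 0.56 at day 6, with 2 of 23 past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.00824, and adjusted p = 0.157 with an estimated correlation); Rtp4 was at 1.97 ± 0.53, a call that ended without any 1 of the day 6 arrays (adjusted p = 0.106 to 0.199) and without the filter (0.0713). Adipocyte genes were higher, 3 up and 1 down of 11, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.179 with an estimated correlation), and lipoprotein lipase Lpl rose by 1.64 ± 0.14. Of 20 glycolysis genes 6 fell, also 6 adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.164 with an estimated correlation), with the aldolase Aldoc at -1.89 ± 0.24 and Eno3 at -1.26 ± 0.09. The interferon call ended at the 60th percentile filter (adjusted p = 0.181, median 0.23). The adipocyte call ended under 6 alternatives, among them no filter (0.0648) and leaving out DMSO replicate 2 (0.0536) or CSA replicate 1 (0.102), and the glycolysis call ended without the trend (0.127), without CSA replicate 1 (0.0798, median 0.01) and without the probe sets that can read several genes (0.147, median 0.03). Sprr1b, Apcs and Ly6i were the other genes with the largest rise, between 3.57 and 3.27, and the largest falls were of Gpr20, Acsl6, Postn, Heph, Ucn3, Gm2137, Vil1, Cox6b2, Saa1 and Aldoc, between -3.01 and -1.89. Periostin (Postn), a matrix protein, changed by -2.57 ± 0.28 (adjusted p = 0.000298). With a floor at a log2 signal of 5 Apcs was at 1.03 (adjusted p = 0.0864), Sprr1b at 1.99 and Ly6i at 1.99, and the fit of only the 4 arrays compared ended the calls of Apcs (0.109) and Sprr1b (0.0505). Leaving out some 1 array of day 6 ended the calls of Lce3c, Lce1h, Sprr1b and Gm2137.

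Without the trend 694 probe sets passed at day 6, and the calls of Lce3c, Lce1h, Sprr1b, Gpr20, Gm2137, Vil1, Rtp4, Pou5f1 (adjusted p = 0.0822), Cdh1 (0.0635), Krt8, Tet2, Chd4 and Jun ended. The count was 1286 and 1112 without DMSO replicate 1 or 2, 1717 and 1360 without CSA replicate 1 or 2, and 1737 without the probe sets that can read several genes.

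**Figure D2:**
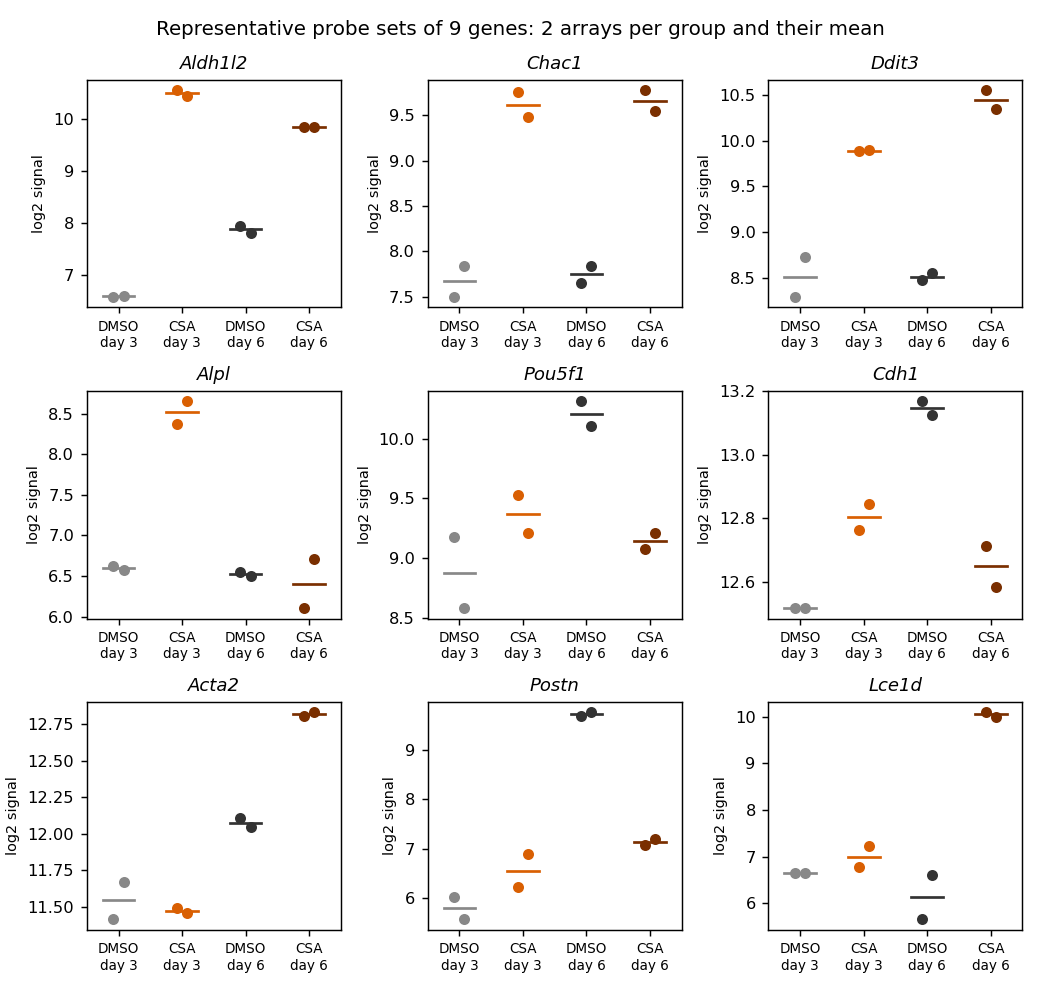
Log2 signals of the representative probe sets of 9 genes in the 4 groups, with each point 1 array and each line the mean of 2 arrays; the vertical axes differ in range and do not start at 0. Aldh1l2, Chac1 and Ddit3 were higher with CSA at both days, Alpl at day 3, and Acta2 and Lce1d at day 6, where Pou5f1, Cdh1 and Postn were lower.

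Calcineurin and its targets were looked at because CSA acts on this pathway. The representative probe sets of the calcineurin subunits Ppp3ca, Ppp3cb and Ppp3r1 did not pass the threshold at either day, with effects between -0.15 and 0.24. Rcan1, an inhibitor of calcineurin that NFAT induces, was at -0.02 ± 0.07 at day 3 (adjusted p = 0.919) and fell by 0.28 ± 0.07 at day 6 (adjusted p = 0.0242). The Rcan1 call at day 6 ended when any 1 of the day 6 arrays was left out (adjusted p = 0.169 and 0.0640 without DMSO replicate 1 or 2, 0.0758 and 0.0829 without CSA replicate 1 or 2). Of 21 tested genes of calcineurin, NFAT and their regulators, 4 rose and 2 fell at day 3 and 4 fell at day 6 (adjusted over the list alone, 5 and 2, and 5). The list passed at neither day (camera adjusted p = 0.426 and 0.263). Nfat5 rose by 0.75 ± 0.12 at day 3, and Rcan3 and Nfatc4 changed by -0.67 ± 0.18 and -0.44 ± 0.11 at day 6. Without the trend the calls of Nfat5, Rcan1, Rcan3 and Nfatc4 ended, and those of Rcan3 (adjusted p = 0.0855 to 0.184) and Nfatc4 (0.0755 to 0.150) also ended without any 1 of the day 6 arrays. Known NFAT targets went both ways, 1 up and 4 down of 16 at day 3 and 3 up and 5 down at day 6 (adjusted over the list alone, 1 and 4, and 4 and 5), and the list passed at neither day (camera adjusted p = 0.426 and 0.534). The cathepsin Ctsk rose at both days, by 1.32 ± 0.10 and 1.51 ± 0.10. Of 12 cyclophilin genes limma called 0 at either day, with 2 at an unadjusted p under 0.05 at each day (camera adjusted p = 0.459 and 0.689).

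Mesenchymal and fibroblast matrix genes did not move as lists. Of 26 mesenchymal genes 3 rose at day 3, and 5 rose and 2 fell at day 6 (adjusted over the list alone, 3 up and 1 down, and 11 up and 6 down), with camera adjusted p of 0.592 and 0.106. At day 3 the list's median was -0.01, its mean 0.09 and camera's direction up. N-cadherin (Cdh2) rose by 1.13 ± 0.08, Snai2 by 0.59 ± 0.12 and vimentin (Vim) by 0.36 ± 0.07 at day 6, and the calls of Snai2 and Vim ended without the trend and without some 1 array of day 6. Of 35 matrix genes 4 rose and 4 fell at day 3, and 8 rose and 7 fell at day 6 (adjusted over the list alone, 6 and 5, and 8 and 9), with camera adjusted p of 0.395 and 0.915; at day 6 the median was 0.02 and the mean -0.11. Col1a2 rose by 0.70 ± 0.06 at day 3, and Fbln5 rose by 1.26 ± 0.10 while Col3a1 changed by -0.85 ± 0.08 at day 6. Keratinocyte genes at day 6 numbered 5 up and 1 down of 15, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0713), with Krt6a at 1.66 ± 0.12 and Lgals7 at -1.48 ± 0.10.

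Over both days together, with 4 arrays against 4 and day as a covariate, 2093 probe sets differed between the treatments, 1149 higher and 944 lower with CSA. Effects at the 2 days, which share no array, overlapped. In all, 259 genes rose at both days where independent lists of these lengths would share 57.4. A further 162 fell at both where they would share 42.3. Opposite calls numbered 53 genes up at day 3 and down at day 6 (54.7 for independent lists) and 15 the other way (44.4). The calls at both days use the same spread of a gene over all groups, so they are not independent. A gene with a low spread passes more easily at each day. The counts for independent lists can thus be too low, and 53 against 54.7 does not show a chance level. A shared spread favours no direction, and genes called in the same direction outnumbered those called in opposite directions. Across 12529 genes, which are not independent replicates, the correlation of the effects was 0.203 (Pearson) and 0.212 (Spearman). It was 0.0387 without the filter on dim probe sets and 0.328 at the 60th percentile filter. The count over both days was 544 without the trend, 1315 without the probe sets that can read several genes, 1337 and 1218 without CSA replicate 1 or 2 of day 3, and 1289 and 1332 without DMSO replicate 1 or 2 of day 6.

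**Figure D3:**
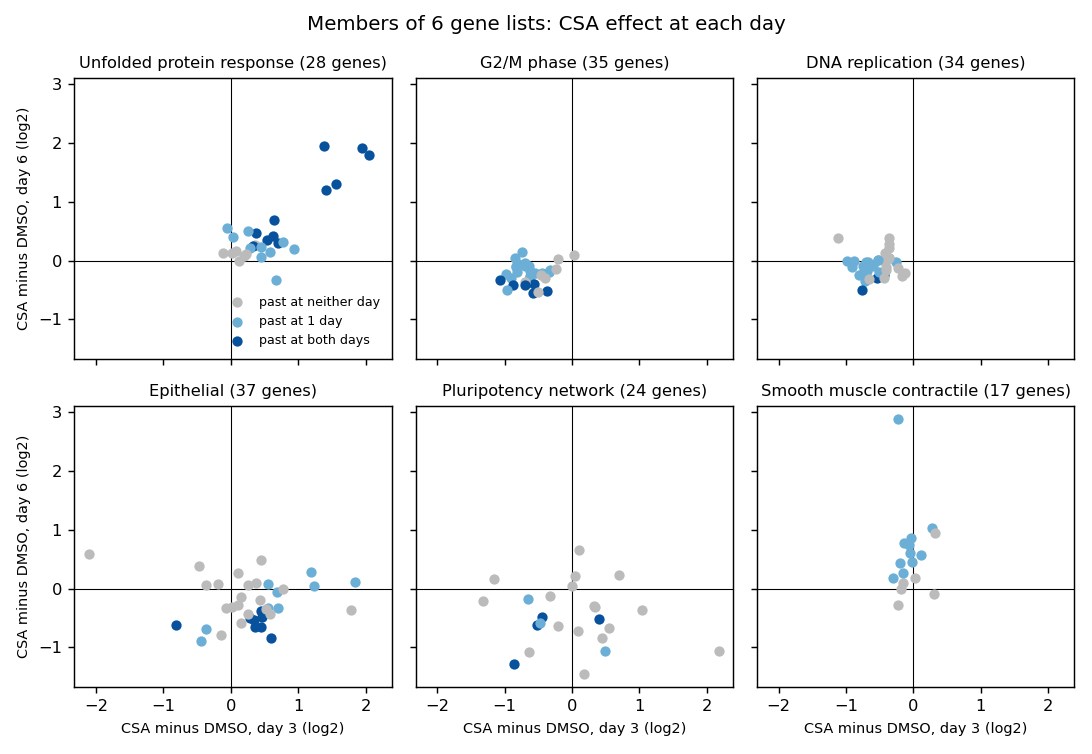
Log2 difference between CSA and DMSO at day 3 (horizontal) and day 6 (vertical) for the tested genes of 6 lists, with each point 1 gene, coloured by whether it passed the threshold at neither day, 1 day or both. The 28 unfolded protein response genes had medians of 0.44 and 0.28, the 35 G2 and mitosis genes -0.63 and -0.22, and the 17 smooth muscle genes -0.07 and 0.46.

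Whether the effect of CSA differed between the days was tested as the interaction. The difference between CSA and DMSO was lower at day 6 than at day 3 for the epithelial list and Pou5f1, and higher for the contractile and cell division lists. For the cell division lists, lower with CSA at day 3, this was mostly a weaker fall at day 6. The cell division calls ended when the correlation was estimated (adjusted p = 0.115 with an estimated correlation for each). The effect on Pou5f1 was 0.49 ± 0.18 at day 3 (adjusted p = 0.130) and -1.07 at day 6, a difference of -1.56 ± 0.26 (adjusted p = 0.00907). For Cdh1 the difference was -0.79 ± 0.09 (adjusted p = 0.00171), and for Alpl, at -0.12 ± 0.29 at day 6, it was -2.04 ± 0.41 (adjusted p = 0.0211). The Pou5f1 call ended without CSA replicate 1 of day 3 (adjusted p = 0.0506), and that of Alpl ended in 5 of 8 fits without 1 array (0.0510 to 0.105). In all, 1144 probe sets passed, 498 with an effect higher at day 6 and 646 with one lower. They represented 296 and 430 genes.

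The interaction held with an estimated correlation for the epithelial and the smooth muscle list. Of 37 epithelial genes 12 had a lower effect at day 6, and 2 a higher and 18 a lower one adjusted over the list alone (median -0.69, camera adjusted p = 1.58e-09, adjusted p = 0.0411 with an estimated correlation), with Dsg2 at -1.72 ± 0.18 and St14 at -1.43 ± 0.13. Of 17 smooth muscle genes 11 had a higher effect, 12 adjusted over the list alone (median 0.48, camera adjusted p = 7.42e-10, adjusted p = 0.0411 with an estimated correlation), with Actg2 at 0.91 ± 0.14 and Acta2 at 0.81 ± 0.12. DNA replication genes had a higher effect at day 6, 8 of 34 and 17 adjusted over the list alone (camera adjusted p = 1.40e-11), as did G2 and mitosis genes, 10 of 35 and 12 adjusted over the list alone (camera adjusted p = 1.58e-09). With an estimated correlation neither held (adjusted p = 0.115 with an estimated correlation for each). In both lists the higher effect was mostly a weaker fall with CSA, and the DNA replication list did not pass at day 6 alone. The effect on Mcm5 was -0.98 at day 3 and -0.0067 at day 6, and that on Aurka -1.07 and -0.33. Mcm5 differed by 0.97 ± 0.10 and Aurka by 0.74 ± 0.13, a call that ended in 2 of 8 fits without 1 array (adjusted p = 0.0510 to 0.0591). Immediate early genes had a lower effect at day 6, 6 of 24, or 1 up and 8 down adjusted over the list alone (camera adjusted p = 2.41e-05), as did early reprogramming markers, 4 of 20, or 1 up and 8 down adjusted over the list alone (camera adjusted p = 0.00122), both at an adjusted p = 0.115 with an estimated correlation. Heat shock genes had a higher effect, 3 of 15 and 5 adjusted over the list alone (camera adjusted p = 0.000180, and adjusted p = 0.271 with an estimated correlation), with Cryab at 0.83 ± 0.09. NRF2 genes did too, 2 of 24 and 6 adjusted over the list alone (camera adjusted p = 0.00276, and adjusted p = 0.165 with an estimated correlation), a call that ended without the probe sets that can read several genes (adjusted p = 0.0521). Without the trend limma called 0 probe sets for the interaction, with 4287 at an unadjusted p under 0.05 against 5048 with the trend. Its count was 390 and 405 without CSA replicate 1 or 2 of day 3, 524 and 434 without DMSO replicate 1 or 2 of day 6, and 568 without CSA replicate 2 of day 6.

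The comparison of day 6 with day 3 in DMSO followed the cells without the inhibitor. All arrays received doxycycline, so changes from reprogramming and from time in culture cannot be told apart here. The epithelial, immediate early and matrix lists were higher at day 6, and those of oxidative phosphorylation and DNA replication lower. None of these calls held when the correlation was estimated (adjusted p = 0.0562 to 0.107 with an estimated correlation). The claudins Cldn7 and Cldn4 rose by 3.55 ± 0.13 and 2.70 ± 0.10, Fos by 4.84 ± 0.16, fibronectin (Fn1) by 2.64 ± 0.07, the pluripotency factor Tfcp2l1 by 2.54 ± 0.30, Epcam by 1.98 ± 0.14 and Pou5f1 by 1.33 ± 0.18. Thy1, a fibroblast surface marker, rose by 1.82 ± 0.11. The genes with the largest rise were Tac2, a tachykinin, at 8.20 ± 0.47 from a day 3 mean of 1.93, Slc17a6, Pdlim4, Saa1 and Tent5c, and those with the largest fall were Apcs, U90926, H3c11, Rnls and Kpna7. With a floor at a log2 signal of 5 Tac2 was at 5.12, and the Rnls call ended in 3 of 4 fits without 1 array (adjusted p = 0.0550 to 0.214). Of 10970 probe sets past the threshold, 6427 were higher and 4543 lower at day 6, 58.6% higher. All tested probe sets had a median shift of 0.098 between the days, which quantile normalization turned to -0.035 and median centring to -0.152, so that 48.3% and 34.9% of the calls were then higher. The direction of small changes between days therefore depends on the scaling, and Myc, whose probe set was not checked for reading the transgene, was at 0.23 ± 0.08 and at -0.02 after median centring. The Myc call also ended without the filter (adjusted p = 0.0655) and in all 4 fits without 1 array (0.110 to 0.170).

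Of the 37 lists 16 passed with camera in DMSO, 9 higher and 7 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.0562 with an estimated correlation. Epithelial genes numbered 28 up and 1 down of 37, 29 and 1 adjusted over the list alone (median 1.58, camera adjusted p = 1.09e-09). Immediate early genes numbered 22 up and 1 down of 24, the same adjusted over the list alone (median 1.42, camera adjusted p = 3.20e-10), and fibroblast matrix genes 27 up and 5 down of 35, also the same (median 1.35, camera adjusted p = 1.63e-08). Each of these 3 lists had an adjusted p = 0.0562 with an estimated correlation. Pluripotency genes numbered 14 up and 2 down of 24, 14 and 2 adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.107 with an estimated correlation). Higher at day 6 as lists were also growth factor signalling, mesenchymal, early reprogramming, TGF-beta response and cell adhesion genes, with camera adjusted p between 0.00112 and 0.0119 (adjusted p = 0.102 to 0.114 with an estimated correlation). Of 46 oxidative phosphorylation genes 36 fell and 1 rose, 38 and 1 adjusted over the list alone (median -0.36, or -0.14 after quantile normalization and -0.61 after median centring, camera adjusted p = 2.97e-11, and adjusted p = 0.0685 with an estimated correlation), with cytochrome c (Cycs) at -0.98 ± 0.06. Of 34 DNA replication genes 25 fell, 29 adjusted over the list alone (camera adjusted p = 3.84e-09, and adjusted p = 0.107 with an estimated correlation), with Mcm5 at -1.13 ± 0.07. Heat shock, G2 and mitosis, NRF2, cholesterol synthesis and smooth muscle genes were lower as lists, with camera adjusted p between 5.74e-05 and 0.0373 (adjusted p = 0.107 to 0.148 with an estimated correlation). Quantile normalization ended the calls of cholesterol synthesis (adjusted p = 0.0652) and smooth muscle (0.504), and without DMSO replicate 2 of day 6 the smooth muscle list was at 0.0569. The smooth muscle call also ended without the filter (0.0675), at the 60th percentile filter (0.0580), without the trend (0.0628) and with the mean of a gene's probe sets (0.0870). That of cholesterol synthesis also ended with the mean of a gene's probe sets (0.212) and without the probe sets that can read several genes (0.0938).

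In CSA the comparison of days asked how the cells changed under the inhibitor, again with reprogramming and time in culture not told apart. The matrix, immediate early and epithelial lists were higher at day 6 here too, calls that ended when the correlation was estimated (adjusted p = 0.0594 to 0.0731 with an estimated correlation). Pou5f1 (-0.23 ± 0.18, adjusted p = 0.396) and Cdh1 (-0.16 ± 0.07, adjusted p = 0.0986) did not pass the threshold. Fos rose by 4.33 ± 0.16, Cldn7 by 2.61 ± 0.13, Fn1 by 2.11 ± 0.07, Epcam by 1.65 ± 0.14 and the smooth muscle actin Acta2 by 1.35 ± 0.08. In DMSO Acta2 was higher at day 6 as well, with log2 signals of 12.11 and 12.04 against 11.41 and 11.67 at day 3. With CSA, Alpl fell by 2.11 ± 0.29. Tac2, Lce3c, Slc17a6, Lbp and Saa1 had the largest rise, between 5.50 and 4.53, and U90926, Epha8, Apcs, Acsl6 and 6330409D20Rik the largest fall. With a pseudocount of 32 Tac2 was at 3.25 and Epha8 at -1.42, and the Epha8 call ended without CSA replicate 1 of day 3 (adjusted p = 0.0527). Of 8358 probe sets past the threshold, 4899 were higher and 3459 lower at day 6, 58.6% higher, or 49.0% after quantile normalization and 31.2% after median centring. The count was 5417 without CSA replicate 1 of day 3.

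In CSA 11 lists passed with camera between the days, 8 higher and 3 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.0594 with an estimated correlation. Matrix genes numbered 27 up and 2 down of 35, 28 and 3 adjusted over the list alone (camera adjusted p = 8.38e-13), and mesenchymal genes 20 up and 1 down of 26, 21 and 2 adjusted over the list alone (camera adjusted p = 3.69e-07), each at an adjusted p = 0.0594 with an estimated correlation. Epithelial genes numbered 20 up and 4 down of 37, 21 and 5 adjusted over the list alone (median 0.79, camera adjusted p = 0.00106, and adjusted p = 0.0731 with an estimated correlation). Immediate early, growth factor signalling, inflammatory, cell adhesion and interferon response genes were also higher, with camera adjusted p between 2.73e-08 and 0.0149 (adjusted p = 0.0604 to 0.173 with an estimated correlation). Of 46 oxidative phosphorylation genes 35 fell and 1 rose, 40 and 1 adjusted over the list alone (camera adjusted p = 2.54e-14, and adjusted p = 0.0594 with an estimated correlation). Cholesterol synthesis and unfolded protein response genes were lower, 1 up and 8 down of 20 and 4 up and 12 down of 28 (adjusted over the list alone, 1 and 10, and 4 and 12), with camera adjusted p of 0.00190 and 0.0149 (adjusted p = 0.128 with an estimated correlation for each). The last of these calls ended under quantile normalization (adjusted p = 0.347), and the interferon call at the 60th percentile filter (0.162), and both ended without the probe sets that can read several genes (0.107 and 0.0590).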

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

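Of the tests in this part, the one on other groupings of the arrays was planned, and both tests of different DMSO arrays were chosen only after the result was seen.

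The effect of CSA differed between day 3 and day 6, by limma's interaction test, for 498 probe sets that were higher and 646 that were lower at day 6. Among genes with a higher effect at day 6, the differences on the log2 scale were 4.08 for Ly6i, 3.75 for H3c11, 3.73 for 4930571B16Rik, 3.57 for Lce1d and 3.22 for Lce1a2. Among genes with a lower effect they were -3.33 for Postn, -2.94 for Sct, -2.75 for Cxxc4, -2.70 for Tac2 and -2.59 for Ano9, and of the fixed genes -1.56 for Pou5f1, -0.79 for Cdh1 and -2.04 for Alpl. All of these calls ended without the trend. Without the filter those of H3c11 (adjusted p = 0.0757), 4930571B16Rik (0.0889), Sct (0.0955), Cxxc4 (0.0876) and Tac2 (0.102) ended, and under quantile normalization those of H3c11 (0.0665) and 4930571B16Rik (0.0689), and under median centring those of Sct (0.0530) and Tac2 (0.0508). With a pseudocount of 32 the differences were 2.38 for Ly6i, 2.08 for H3c11, 2.12 for 4930571B16Rik, -1.75 for Tac2, -1.75 for Sct (0.0514) and -1.27 for Cxxc4 (0.0845). With a floor at a log2 signal of 5 Cxxc4 was at -1.10 (0.244), Sct at -2.16 (0.0679), Tac2 at -1.68 and H3c11 at 2.35. Of 8 fits without 1 array, 8 ended the calls of Sct and 4930571B16Rik, 7 that of H3c11, 6 that of Cxxc4, 5 those of Tac2 and Alpl, 3 that of Ano9, and 1 those of Lce1a2 and Pou5f1. Whole lists differed by medians of -0.69 for epithelial genes, -0.59 for early reprogramming markers, -0.46 for immediate early genes, 0.34 for G2 and mitosis genes, 0.49 for DNA replication genes, 0.48 for smooth muscle genes, 0.16 for heat shock genes and 0.20 for NRF2 genes. The median of the early reprogramming markers was -0.37 at the 60th percentile filter, and that of the heat shock genes 0.10 and 0.26 without DMSO replicate 1 or 2 of day 3. Of these, the epithelial and smooth muscle lists held when the correlation was estimated (adjusted p = 0.0411 with an estimated correlation for each), and the others did not (adjusted p = 0.115 to 0.271 with an estimated correlation).

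The number of probe sets that separated CSA from DMSO over both days was set against other groupings of the 8 arrays into 4 and 4. Of 35 groupings 34 gave a fit with day as a covariate, and 1 of these, the real one with 2093 probe sets, gave as many. The highest of the others gave 0 by limma, with 387 to 2779 probe sets at an unadjusted p under 0.05 against 5917 for the real one. The other groupings keep the treatment difference in their residual spread, which lowers their counts, so the distance to the real count is no measure of strength. The grouping with 2779 set DMSO at day 3 and CSA at day 6 against the other arrays, which is the interaction.

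At day 3 the CSA effect ran across 12529 genes in the direction of the change from day 3 to day 6 in DMSO (r = 0.336), and at day 6 against it (r = -0.398). Both effects share DMSO arrays with that change, and noise of shared arrays alone gave 0.500 and -0.502 in 100 simulations without any effect. The covariances were 0.120 and -0.148 against 0.0525 and -0.0527 simulated, differences of 0.0680 and -0.0953. With different DMSO arrays in the 2 comparisons the covariances were 0.0528 and 0.0630 at day 3 and -0.0960 and -0.102 at day 6, which argues against noise of single shared arrays as the whole source. A deviation common to both DMSO arrays of a day stays open. So does, as a hypothesis, that CSA cells may have been further along this course at day 3 and less far at day 6. The course holds time in culture as well as reprogramming.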

How the results depend on the processing

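The pseudocounts and the floor were chosen after seeing the data; the planned pseudocount alternatives were void because the values were already log2. With at least 2-fold added the counts were 343 (day 3), 424 (day 6), 218 (both days), 335 (interaction), 3503 (days in DMSO) and 2227 (days in CSA). Without the trend they were 442, 694, 544 and 0 for the first 4, the last with 4287 at an unadjusted p under 0.05. Without probe sets that can read several genes they were 1672, 1737 and 1315 for the first 3; fewer probe sets were tested there. Other causes were not tested. With an estimated correlation the lists past the threshold were 1, 1 and 2 for day 3, day 6 and the interaction, and 0 for both comparisons of days, where camera with the preset value called 16 and 11. The planned test fry called 9 (day 3), 15 (day 6), 9 (interaction), 31 (days in DMSO) and 27 (days in CSA) of the 37 lists. It does not compare a list with other genes, so a shift shared by most genes counts there too.

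Leaving out 1 array gave 1076 to 2008 (day 3), 1112 to 1717 (day 6), 1218 to 1604 (both days), 390 to 994 (interaction), 8106 to 9380 (days in DMSO) and 5417 to 6068 (days in CSA). The lowest came from CSA replicate 2 (day 3, both days), DMSO replicate 2 of day 6 (day 6) and CSA replicate 1 of day 3 (interaction, days in CSA). The correlation of the effects was 0.0387 without a filter, 0.328 at the 60th percentile filter, 0.213 after quantile normalization, 0.184 without probe sets that can read several genes, 0.229 and 0.260 with pseudocounts of 8 and 32, 0.243 with the floor, and 0.174 to 0.195 without 1 array. Dim probe sets carry the most noise.

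Replicate numbers did not pair the arrays: differences between replicates correlated between groups at -0.00344 to 0.0343. With the replicate number as a block the counts were 2724, 2742, 1766, 1208, 11131 and 8516, and of named gene calls 9 ended and 8 were added. Among those that ended were the interaction calls of Sct and Tac2. Of named gene results 259 lost their call with the same direction without the trend, 30 under median centring, 31 under quantile normalization, 39 without a filter and 33 in the fit of 4 arrays; over all fits without 1 array calls ended 699 times. Myc between days in DMSO turned to -0.0221 under median centring and Stmn2 to 0.0047 under quantile normalization, and these calls ended too. The median of the glycolysis list at day 6 turned to 0.0250 without probe sets that can read several genes and to 0.0071 without CSA replicate 1 of day 6, where its call ended. Of list calls, 4 ended under quantile normalization and 9 without probe sets that can read several genes.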

Other observations

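All tests in this part were chosen only after the result was seen, as were the gene groups beyond the fixed lists. Leaving out arrays and changing the scaling were planned settings. Their use on the Lce genes was not planned, because that group was picked after the result was seen.

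Genes induced by the transcription factor ATF4, which directs amino acid synthesis and transport under stress, rose broadly with CSA; this group was written after the tables were seen. Of 38 tested genes 34 rose at day 3 and 21 at day 6, with medians of 0.70 and 0.57, and the counts were 32 and 23 under quantile normalization and 33 and 22 under median centring. Examples at day 3 and day 6 were Atf5 at 2.26 and 2.06, Trib3 at 2.05 and 1.79, the serine synthesis enzyme Psph at 1.69 and 1.27, and Pck2 at 2.22 and 0.59. Because this group was picked from the same data, its count is a description and no test.

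Most tested late cornified envelope (Lce) genes and many other genes of terminal epidermal differentiation were higher with CSA at day 6. Of 15 Lce genes listed 11 were tested. The filter used the mean over all arrays, so a gene high in the CSA arrays of day 6 was more likely to be tested. Of the 11 tested Lce genes 10 rose at day 6. At day 3 limma called 0 of them, with 1 at an unadjusted p under 0.05. The interaction passed for 5. Of 17 other cornified genes 11 rose and 1 fell at day 6, with a median of 1.62; involucrin (Ivl) rose by 2.37, Crct1 by 2.00, the protease gene Asprv1 by 1.94 and Klk6 by 1.88, while transglutaminase Tgm1 fell by 0.39. Both groups were picked from the same data, so these counts are a description and no test.

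A rise of the Lce genes could come from probe sets that read several paralogs, from 1 array or the scaling, or from a larger share of keratinocytes. Of 12 Lce probe sets the 6 with plain IDs, which are not marked as shared between genes, all rose, which argues against shared probe sets as the whole source, although probe sequences were not examined. At least 7 of the 11 genes passed when 1 day 6 array was left out or the scaling or pseudocount was changed, the fewest without CSA replicate 2. The median change of 9 keratinocyte genes outside the cornified envelope was -0.0459 (SE 0.444) against 3.10 for the Lce genes. But 6 of the 9 started in DMSO above 9.16, the median log2 level that the Lce genes reached with CSA. A small added share could be hidden there, although levels of different probe sets compare only roughly. So a small number of added keratinocytes and a change of state within cells already present cannot be told apart here.

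The unfolded protein response genes that rose at both days could belong to the ATF4 branch alone. The 17 chaperones, folding enzymes and degradation factors of the fixed list had a median of 0.334 (SE 0.141) at day 3 and 0.312 (SE 0.113) at day 6. The rise was thus not limited to the 8 genes of the list that were set apart as ATF4 or CHOP targets. These SEs run over genes, which are not independent replicates, and whether ATF4 also induces some of the 17 was not examined. So the medians cannot decide whether that branch acted alone. Of the 17, 8 passed at day 3 and 9 at day 6, and the chaperones and folding enzymes Hspa5, Hsp90b1, Calr, Pdia3 and Pdia4, singled out after their values were seen, passed at neither day. The 8 genes set apart as ATF4 or CHOP targets, Atf4 included, had medians of 0.644 (SE 0.308) and 0.316 (SE 0.412). What sets off the response stays open.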
